A study of Mus musculus with 4 samples.

How the data were processed

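Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in the paraventricular nucleus of the hypothalamus (PVH) of 12-week-old mice. Per the labels, all mice carried loxP-flanked alleles of Otp and the Ai14 reporter. They had received an adeno-associated virus (AAV) as adults and were dissected 4 weeks after the injection. 2 libraries came from mice given AAV-GFP (control) and 2 from mice given AAV-Cre, which deletes Otp in infected cells. Per the labels' protocols, nuclei were released by douncing, pelleted through sucrose and tagmented with a commercial ATAC kit, and no sorting of infected cells is named. The labels give no sex, and do not say how many animals went into a library or that the libraries came from separate animals, so the spread between libraries may be technical.

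Per the submitters' processing notes, FastQC, Trim Galore, Bowtie2 and MACS2 were used and the genome build was mm10. Versions, read filters, a shift of reads for the transposase and the peak threshold are not given in the sources used here. The lowest −log10 q in the 4 deposited library lists lay between 1.303 and 1.312, close to a q of 0.05. The authors deposited 6 peak lists, 1 for each library and 1 for each group. In each, the start, end and summit of a peak are in bp. The deposited score is the whole part of 10 times −log10 q. The fold enrichment is the authors' ratio of signal at the summit to background, and −log10 p and −log10 q are the authors' values for each peak. Fold enrichment and −log10 p were used only to describe, rank or filter peaks within their own list. The 2 group lists carry peak names that mark them as called on a pool of the group, and 100% of their peaks overlapped peaks of both libraries of their own group. No read counts were used here, so the sequencing depth of each library is unknown. The number of peaks in a list can depend on depth. Whether reads were reduced to equal depth before peaks were called is not given in the sources used here, and if they were, differences in list length are not differences in depth.

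Peaks of the 4 libraries that shared at least 1 bp were merged into regions. A region was control-specific when both AAV-GFP libraries and neither AAV-Cre library had a peak in it, and Cre-specific in the converse case. Because list length alone can make a region specific, all counts were repeated with each list reduced to its 23384 strongest peaks by −log10 p, the length of the shortest list. Equal lengths also pull the control-specific and Cre-specific counts toward each other by construction, so the ratio of these counts does not measure a gain or loss by itself. The 4 libraries can be split 2 against 2 in 3 ways, so the smallest exact p for any comparison of the groups is 0.333 and none can reach 0.05. Counts for the other splits were given beside the real one.

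Genes and coordinates came from a RefSeq gene table of the same build, with 21887 protein-coding genes. The table gave gene starts and ends without strand, transcripts or exons. The planned promoter window of 1 kb to each side of a transcription start site was therefore replaced by a window of 1 kb to each side of both ends of a gene, called the gene-end window, so a peak there lies at the start or the end of the gene. In the first AAV-Cre library, 9391 genes had a peak at one end and 571 at both. As a check of the build, 24.1% of gene-end windows held a peak of that library, against 3.7% after a shift of 100 kb. The planned test of 17 sequence motifs in control-specific regions was not run, because no genome sequence was used here.

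Before the data were examined, 16 gene lists with 265 entries were fixed, of which 264 matched the gene table. They cover PVH peptides and transcription factors, melanocortin signalling, neighbouring nuclei, neurons, glia, vessels, ependyma, inflammation, cell stress, neuronal activity and housekeeping. For each list, regions with a peak in both AAV-GFP libraries within 10 kb of a member gene were taken, and the share absent from both AAV-Cre lists was compared with 10000 random sets of regions near protein-coding genes. The sets were matched on decile of control peak strength and on gene-end or other position. The p-values were 2-sided and adjusted by the Benjamini-Hochberg method over the 16 lists. Regions are not replicates, so these tests describe the 4 libraries and not the animals. On simulated lists of 20 genes for the same comparison, the test found 0% of lists with unchanged odds of loss. It found 5.5% at odds of 2, 61.5% at odds of 4 and 90.5% at odds of 8. In each simulated run every list carried the same odds and was adjusted only with the others of its run. The 16 real lists need not all differ and held 5 to 94 regions, so these shares may overstate detection among them. Shares of regions carry 95% Wilson intervals, which cover counting error only. Fisher's exact tests across regions were 2-sided.

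The groups, gene lists, alternatives and the rule for named genes were also fixed before the data were examined. Genes named are Mc4r, Otp and Sim1, list members with a control-specific or Cre-specific gene-end window, and the 12 control-specific and 12 Cre-specific genes with the strongest peaks among those specific both in the deposited and in the equal-length lists. Strength was the weaker of the 2 within-list rank percentiles. Some genes that this rule takes are counted but not reported here by name. The 5 strongest regions of each kind were named by the same rule. Other genes were chosen after their values were seen. Alternatives were lists of equal length, a −log10 q of at least 5, stricter definitions of overlap, other windows, each library left out in turn, a replicate block and the authors' group lists. Reading genes by merged region and leaving out the ends of X and Y were added after the data were seen. Overlaps were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. The merging was checked with bedtools 2.31.1, which gave the same 67299 regions, and plots were drawn with matplotlib 3.10.9.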

Results

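Open chromatin was profiled in the PVH of 2 AAV-GFP control and 2 AAV-Cre Otp knockout libraries, as peak lists on the mm10 build. The study set out to locate the open promoter chromatin of Mc4r, the melanocortin receptor through which the PVH restrains feeding, and to ask whether adult loss of Otp, a homeodomain transcription factor of hypothalamic neurons, lowers accessibility near its targets. The control lists held 57682 and 34100 peaks and the AAV-Cre lists 23384 and 26612. The mean was 45891 ± 16675 (SD, n = 2) in controls and 24998 ± 2282.5 (SD, n = 2) after AAV-Cre, a ratio of 1.84 with an exact p of 0.333, the smallest that 3 splits allow. Peaks covered 16778 and 12698 kb in the controls and 8096.8 and 9482.5 kb in the AAV-Cre libraries. Median fold enrichment, the authors' own value for each peak, was alike, at 5.59, 5.85, 5.72 and 5.77 in the same order.

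The Otp locus itself, on chromosome 13 from 94875636 to 94885125, kept open chromatin in part. A region at 94875130 to 94875565, 70 bp outside the lower end of Otp, had a peak in both controls (fold enrichment 3.73 and 4.22) and in AAV-Cre replicate 2 (5.52), but none in AAV-Cre replicate 1. A region inside Otp, at 94883175 to 94883578, had a peak in both controls (4.89 and 5.60) and in neither AAV-Cre library. Another inside Otp, at 94877155 to 94877338, had a peak in AAV-Cre replicate 1 alone (4.31), and one 178 bp past the upper end had a peak in AAV-Cre replicate 2 alone (3.46). Within 100 kb of Otp, 8 regions were seen, of which 3 were shared by all 4 libraries and 1, that at 94883175, was control-specific. It was not control-specific in lists of equal length or at a −log10 q of at least 5. Its peak in AAV-GFP replicate 1, with a −log10 q of 4.66, itself fell below both cuts. The labels do not state which part of Otp is flanked by loxP, so these peaks do not check the deletion. A region 6545 bp outside the lower end of Otp, at 94868573 to 94869090, had a peak in all 4 libraries. There the authors' deposited control group list held a peak with a fold of 9.22 and the AAV-Cre group list a peak with a fold of 8.43. The control group list also held peaks at 94875073 (4.61) and inside Otp at 94883169 (5.63), where the AAV-Cre group list held none.

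Mc4r, on chromosome 18 from 66857705 to 66860487, had 1 region of open chromatin shared by all 4 libraries. It spans 66860348 to 66860676 and overlaps the upper end of the gene. The fold enrichment was 11.6 and 6.08 in the controls and 4.61 and 4.97 in the AAV-Cre libraries, with a −log10 q of 20.6, 6.61, 3.27 and 3.83. At a −log10 q of at least 5 this region was therefore control-specific, while as deposited and in lists of equal length the locus had 0 control-specific regions. Among the 14634 regions shared by all 4 libraries, its rank percentile, counted from the strongest, was 51.4 and 85.4 in the controls and 93.3 and 91.5 after AAV-Cre. The mean shift of 24 percentile points toward weaker rank compares with an SD of 16.4 over all shared regions, and 7.08% of shared regions shifted as far. The 2 controls differed from each other by 34 points, more than the shift between groups. The authors' deposited group lists gave the Mc4r peak a fold of 10.7 in the control pool and 5.88 in the AAV-Cre pool. A further region at 66844688 to 66844854 had a peak in AAV-GFP replicate 1 alone.

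**Figure D1:**
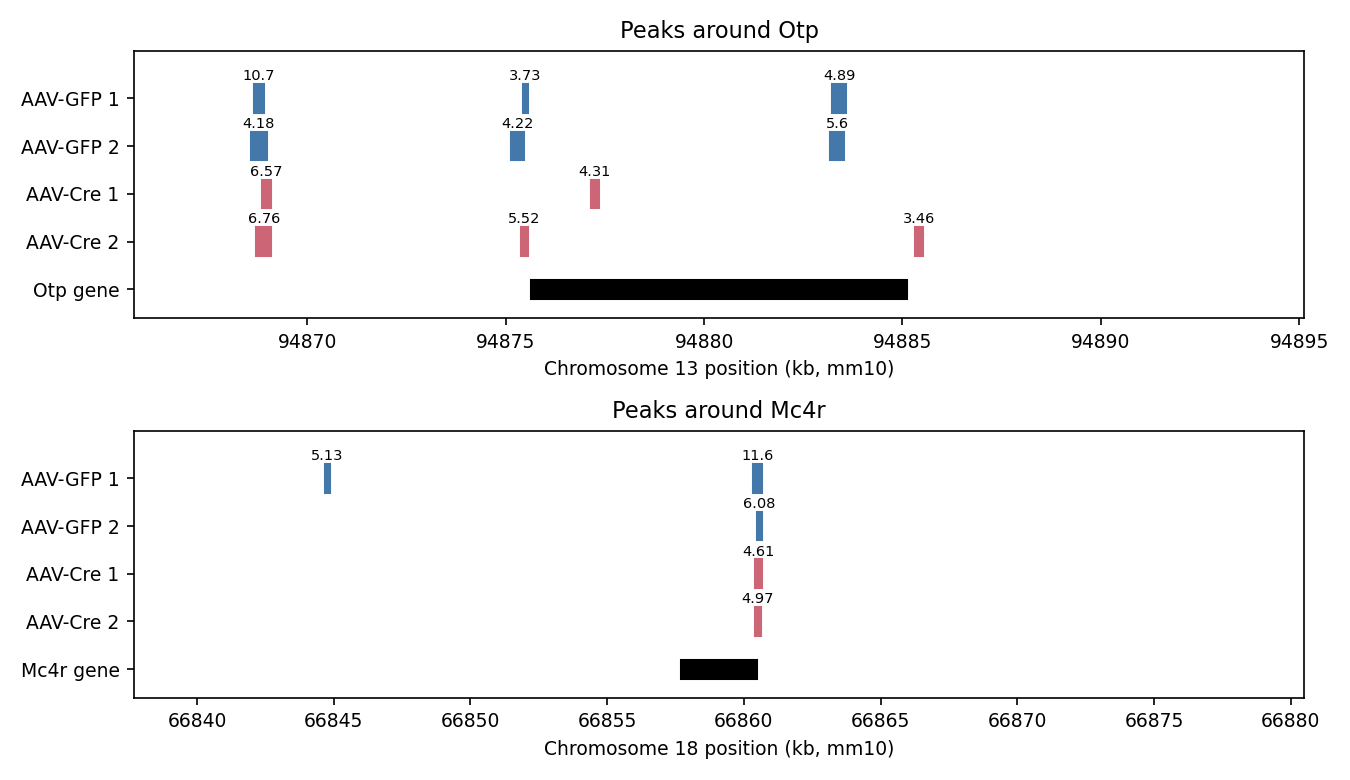
Peaks around Otp and Mc4r in each library, drawn to scale along the chromosome in kb, with the authors' fold enrichment above each peak and the gene as a black bar. The peak at the upper end of Mc4r is present in all 4 libraries, and the peak inside Otp at 94883175 is present in both AAV-GFP libraries and neither AAV-Cre library.

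At genes of the PVH neuroendocrine programme, control peaks were absent after AAV-Cre at some members and present at others. Sim1, a transcription factor required for PVH development, had a control-specific region at chromosome 10, 50894310 to 50894660, 37 bp outside the gene and overlapping A230054N11Rik, with folds of 4.73 and 4.03. Trh, which encodes thyrotropin-releasing hormone, had a control-specific peak at its gene-end window (6.38 and 4.63), and so did Npy1r, a neuropeptide Y receptor (7.46 and 4.76). A region 6664 bp from Trh had the opposite pattern, with folds of 7.35 and 5.14 in the AAV-Cre libraries alone. This region was still Cre-specific in lists of equal length. At a −log10 q of at least 5 its peak in AAV-Cre replicate 2 (4.27) fell below the cut. Crh, which encodes corticotropin-releasing hormone, had a gene-end peak in AAV-GFP replicate 1 (10.3) and AAV-Cre replicate 2 (4.42). The transcription factor gene Foxp2 was Cre-specific (4.11 and 4.07). In lists of equal length and at a −log10 q of at least 5, Sim1, Trh and Npy1r were not control-specific and Foxp2 was not Cre-specific. At equal length the cut itself decided this. The peaks of AAV-GFP replicate 2 at Sim1, Trh and Npy1r stood at percentiles 94.4, 84.3 and 82.2, and 68.6% of that list was kept. That of AAV-Cre replicate 2 at Foxp2 stood at 94.3, and 87.9% was kept. The equal-length result thus does not count against a group difference at these genes.

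Across the genome, regions open in both controls and absent after AAV-Cre outnumbered the converse. Of 67299 regions, 14634 (21.7%) were shared by all 4 libraries, 7728 were control-specific and 796 were Cre-specific, a ratio of 9.71. The strongest control-specific region lay in Efl1, a gene of ribosome maturation, at chromosome 7, 82771080 to 82771809, with folds of 26.8 and 17.2. The next 4 lay near the ends of the sex chromosomes. They were on Y at 90721906 to 90723388 (12.7 and 12.2), on X at 169990955 to 169991590 beside Mid1 (5.01 and 5.23), on X at 170004187 to 170004775 (4.56 and 4.70) and on Y at 90765231 to 90765825 (5.76 and 4.14). The strongest Cre-specific region lay in Fkbp6 at chromosome 5, 135326124 to 135326748, with folds of 9.87 and 10.2. It was followed by regions at chromosome 11, 71649557 to 71650046, nearest Wscd1 (9.19 and 9.32), chromosome 13, 93036178 to 93036546, near Cmya5 (8.76 and 8.32), chromosome 17, 27248568 to 27248978, nearest Lemd2 (9.46 and 8.29), and chromosome 2, 59485682 to 59485963, in Dapl1 (9.25 and 7.82).

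The surplus of control-specific regions was smaller in lists of equal length, which pull the counts of the groups together by construction. The change therefore does not show that list length was the cause. In lists of equal length, 2102 regions were control-specific and 1788 Cre-specific, a ratio of 1.18. The groups still parted more regions than other splits of the libraries did. Together 3890 regions followed the groups in lists of equal length, against 1433 and 1498 for the other splits, and as deposited the numbers were 8524 against 1625 and 2290. With 3 splits this has an exact p of 0.333.

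**Figure D2:**
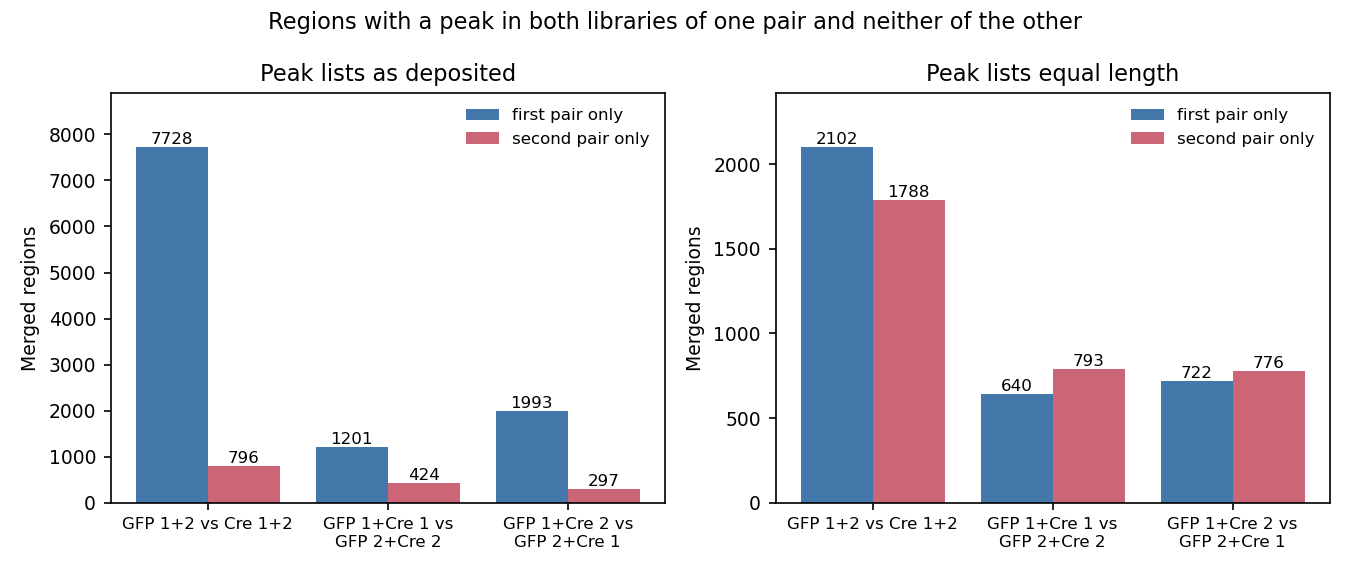
Number of merged regions with a peak in both libraries of a pair and in neither library of the other pair, for the 3 ways to split the 4 libraries, with lists as deposited (left) and of equal length (right). The split by group gives 7728 and 796 regions as deposited and 2102 and 1788 at equal length, more in total than either other split.

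Strong control regions were nearly all kept. Of 3135 regions within the strongest 10% of both control lists, 7 (0.223%) had no peak in either AAV-Cre library, against 65.4% among regions whose weaker control peak fell in the last 10%, and 27% of all 28575 regions shared by the controls. In lists of equal length 12.1% were absent, and 11.3% of regions shared by the AAV-Cre libraries were absent from both controls. Equal length also draws these shares together. Gene ends were sparse among regions not shared by all 4 libraries, whether or not these followed the groups. They made up 12% of control-specific regions (95% Wilson interval 11.3 to 12.7) and 6.28% of Cre-specific regions (4.80 to 8.19), against 54.9% of regions shared by all 4 libraries (54.1 to 55.7). The odds ratio of control-specific against shared regions was 0.112, with a log10 p of -936.7 in the lower tail of Fisher's exact test. Over all patterns of regions missing from at least 1 library it ran from 6.28% to 28.7%. Outside the group split it was 8.61% of regions in AAV-GFP replicate 1 alone and 10.3% in AAV-Cre replicate 2 alone. It was 12.8% and 13.6% in regions that AAV-GFP replicate 1 shared only with AAV-Cre replicate 1 or 2. Shared regions were also wider, with a median of 622 bp against 300 bp for control-specific regions. At equal length the shares were 14.3% and 59.4%.

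**Figure D3:**
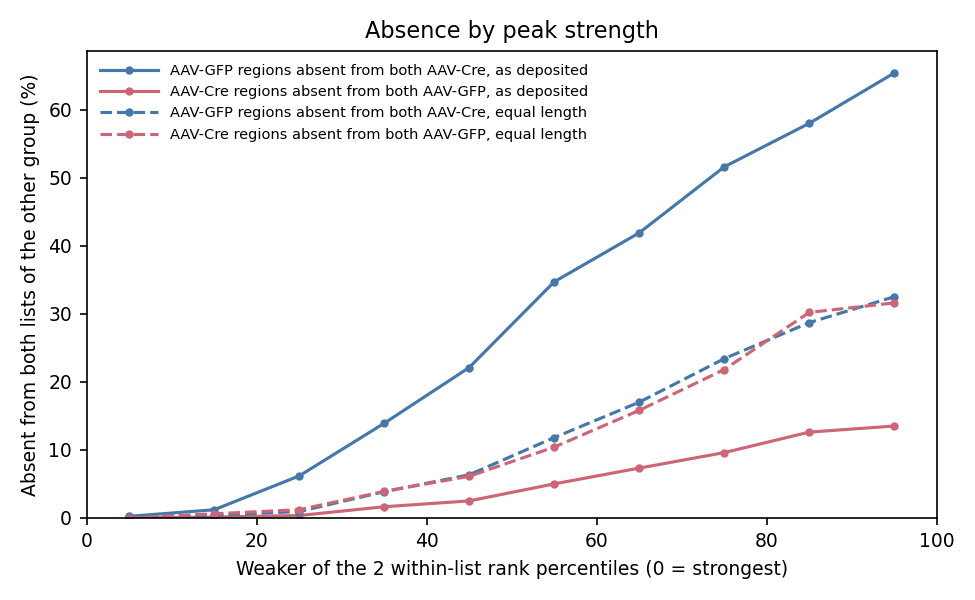
Percent of regions shared by both libraries of a group that had no peak in either library of the other group, by the weaker of their 2 within-list rank percentiles (0 is strongest), for lists as deposited (solid) and of equal length (dashed). Absence of AAV-GFP regions rises from 0.223% to 65.4% as deposited. The AAV-GFP and AAV-Cre curves lie close together at equal length, which equal length favours by construction.

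Most genes had gene-end peaks either in all 4 libraries or in none. Of 21887 protein-coding genes, 9057 had a gene-end peak in all 4 libraries and 9164 in none, while 675 were control-specific and 20 Cre-specific. In lists of equal length the counts were 257 and 152, and 208 and 16 genes were specific in both settings. The strongest of the control-specific genes were Erbb3, a neuregulin receptor (13.1 and 14), Mid1, a ubiquitin ligase (5.01 and 5.23), and Wdr1, an actin regulator (16.1 and 10.1). Sdhc, a subunit of succinate dehydrogenase, had folds of 9.67 and 10.3. Further genes were Exoc3, Sinhcaf, Zfp955b, Vtn, Vbp1, Hpn and Mlf1. For Erbb3, Wdr1, Exoc3 and Vtn, the merged region at the gene also held an AAV-Cre peak that ended outside the gene-end window, and 8 of the 12 genes held when read by merged region. The strongest Cre-specific genes were Erbb2, a receptor kinase (10.1 and 7), Dnah11, an axonemal dynein (5.93 and 6.63), Zfp52 (5.52 and 5.21), Npr3, a natriuretic peptide receptor (5.45 and 5.67), and Ptgds, which encodes a prostaglandin D synthase (4.98 and 6.27). C2cd4d, Fat1, Smcp, Nfam1, Gem and Glmp followed. By merged region 10 of these 12 held, Erbb2 and Zfp52 being the exceptions.

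No gene list passed the test for loss of open chromatin against matched regions. With matched sets, 0 of 16 lists had more loss and 0 had less, 0 passed at an unadjusted p under 0.05 and the lowest adjusted p was 0.75. With an unmatched Fisher's exact test 3 lists passed before adjustment and 1 after, the pan-neuronal list (adjusted p = 0.0028). Among PVH neuropeptide and hormone genes, 6 of 19 control-shared regions (31.6%) were absent from both AAV-Cre lists, against 27.9% in matched sets (10.5 to 47.4). At gene ends 4 of these 20 genes, Ghrh, Vgf, Scg2 and Nppc, had peaks in all 4 libraries, and Trh and Npy1r were control-specific. Of PVH lineage transcription factors, 28.1% of 32 regions were absent against 32.6% (18.8 to 46.9). As deposited, Sim1 and Dach1 were control-specific and Foxp2 Cre-specific. In lists of equal length none of the 3 held, since the cut removed a peak of their own group. Dach1 was not control-specific by merged region either. Pou3f2 and Foxp1 had peaks in all 4 libraries. Of melanocortin and energy balance genes, 18.4% of 38 regions were absent against 23% (13.2 to 34.2). In that list 10 of 20 genes, among them Mc4r, Pomc, Agrp and Mrap2, had gene-end peaks in all 4 libraries, and 0 were control-specific. In all 3 lists the observed share lay inside the range of matched sets.

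Lists of neurons and of other cell types gave no call either. Members are given as control-specific from the deposited lists, and of all 15 list members that were specific there, Tbp alone held in lists of equal length. For each of the others the cut removed a peak of its own group, so this does not show a peak in the other group. Pan-neuronal genes had 40.4% of 94 regions absent against 32.8% (24.5 to 41.5), near the upper bound, and Syp, a synaptic vesicle protein, was control-specific (5.85 and 4.45). Glutamatergic and GABAergic neuron genes had 25% of 44 regions absent against 29%, with Slc17a6, a vesicular glutamate transporter, control-specific (4.95 and 5.96). Genes of neighbouring nuclei had 26.3% against 26% in matched sets, with Dlx2 control-specific. Absence was 30.3% against 32% for astrocyte genes, with Fgfr3 control-specific, 36.8% against 34.1% for oligodendrocyte genes, with Cldn11, and 40% against 30.6% for oligodendrocyte precursor genes, with Pdgfra. Microglia and macrophage genes had 0 of 7 regions absent against 14%, and endothelial and mural genes 4 of 5 (80%) against 43.8% (0 to 80), on the upper bound. For endothelial and mural genes 15 of 15 had no gene-end peak in any library, and for microglia 12 of 16. Ependymal and tanycyte genes had 25% absent against 18%, and inflammation and interferon genes 37.5% against 25.6%, with Ifit3 control-specific. Cell stress and apoptosis genes had 4% of 25 regions absent against 14.8% (4 to 24), although the gene ends of Atf3 and Trib3 were control-specific. With AAV-GFP replicate 1 left out, the share for cell stress genes was 20.7% against 21.6%. Activity-regulated genes had 13.5% against 18.2% and housekeeping genes 12.2% against 11%. Tbp, a housekeeping gene, was control-specific both as deposited (5.89 and 5.59) and in lists of equal length, but not with a gene-end window of 2500 bp.

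**Figure D4:**
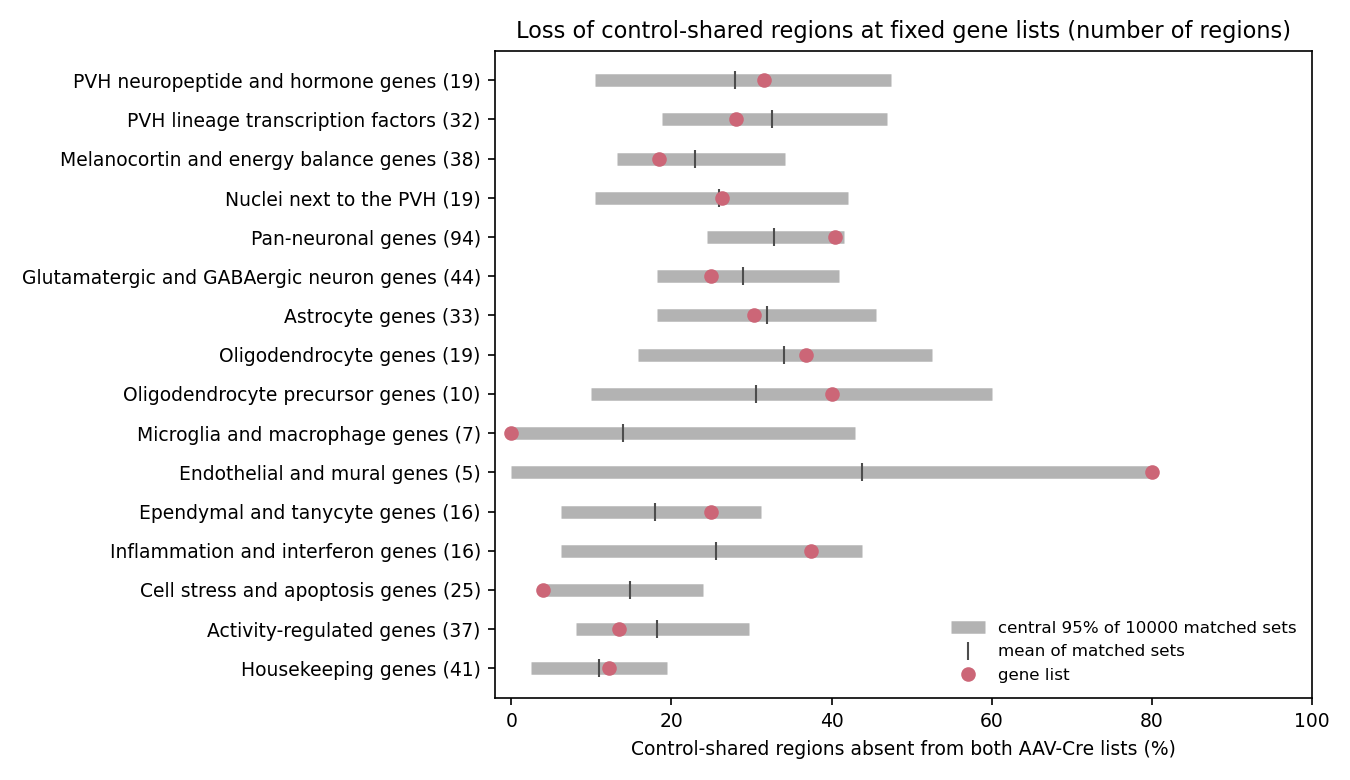
Percent of control-shared regions absent from both AAV-Cre lists for each gene list (points), with the mean (ticks) and central 95% (bars) of 10000 matched sets of regions and the number of regions in parentheses. Pan-neuronal genes, at 40.4%, lie near the upper bound of 41.5, endothelial and mural genes, at 80% of 5 regions, lie on theirs, and no list lies beyond its bar.

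In the lists as deposited, whether peak lists overlapped more within groups than between them depended on the measure. The Jaccard index, the shared fraction of covered bp, was 0.445 between the controls and 0.441 between the AAV-Cre libraries, and 0.321 to 0.427 between groups. The mean difference of 0.0677 had an exact p of 0.333. The share of the shorter list that overlapped went the other way, by -0.425 percentage points (exact p of 1). At equal length this share was 74.95% and 68.84% within groups against 63.68% to 68.33% between them, the same direction as the Jaccard index. At equal length the AAV-Cre libraries had an index of 0.452, below the 0.461 of AAV-GFP replicate 2 and AAV-Cre replicate 2. The authors' deposited group lists held 28592 control and 16614 AAV-Cre peaks. Of the control list, 51.3% overlapped the AAV-Cre list, and 88.5% of the AAV-Cre list overlapped the control list.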

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

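Depth is unknown, as is whether it was made equal before peaks were called, and most counts moved with list length and with the number of libraries that had to hold or lack a peak. Reading genes by merged region and leaving out the ends of X and Y were chosen after the data were seen. Against 7728 control-specific regions, equal length gave 2102 and the authors' group lists 13929, and leaving out a library 10063 to 31691, the highest without AAV-GFP replicate 2. Against 796 Cre-specific regions, the values were 1788 at equal length, 317 at a −log10 q of at least 5, 1903 with the group lists and 1025 to 3949 without a library. Control-specific genes, 675, became 257, 1165 and 2139 in the same order, and 862 to 1512 without a library. Cre-specific genes, 20, became 152, 12, 127 and 46 to 111. Fewer libraries make a region specific more easily, and the cause of the other moves was not tested. Stricter overlap, the added settings and other windows kept these counts within 1.5 times. Gene ends remained sparse among control-specific regions, at 9.10% to 21.8%, in every alternative run.

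The labels give both groups the numbers 1 and 2. With the replicate block the counts were 7728, 796, 675 and 20, the same by construction, and same-numbered libraries were no more alike than others, so the numbers were not read as pairs.

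At Mc4r, 1 region was control-specific at a −log10 q of at least 5, and 0 to 1 without a library. At Otp the count was 0 at equal length, 0 at the stricter q and 1 to 2 without a library. The control minus AAV-Cre share of libraries with a peak at Otp gene ends was -0.5 at equal length, the reverse of the deposited lists. Both control peaks there had fallen below the cut. Of the 15 list members named as specific, 1 held at equal length and 3 at the stricter q. At equal length the rest lost a peak of their own group to the cut. The other 24 named genes were chosen to hold at equal length. Of all 39, 18 held at the stricter q and 27 with each other gene-end window. Within minus between groups, the share of the shorter list that overlapped was -0.425 percentage points as deposited, the reverse of the Jaccard index, with an exact p of 1. At equal length it was 74.95% and 68.84% within groups and 63.68% to 68.33% between them. The reversal was thus absent at equal length, and its cause was not tested further.

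The count of gene lists with more loss was 1 with the unmatched Fisher's exact test and 0 in the other alternatives. Uncalled differences from matched sets changed sign often. Without matching, 4 of 16 lists did so, with 28.1% absent for PVH transcription factors, 25% for glutamatergic and GABAergic, 30.3% for astrocyte and 12.2% for housekeeping genes. With 50 kb flanks, 2 did, oligodendrocyte (26.5%) and ependymal genes (14.7%). At equal length, 5 did, PVH neuropeptide (12.5%), astrocyte (15.4%), oligodendrocyte (18.2%), ependymal (7.69%) and inflammation genes (0%). Leaving out AAV-GFP replicate 1 or 2 or AAV-Cre replicate 1 or 2 turned 0, 3, 6 and 6 lists. The shares then ranged over 36.8% to 50% for PVH neuropeptide genes, 31.2% to 68.2% for PVH transcription factors, 26.3% to 51.9% for melanocortin genes, 31.6% to 57.9% for neighbouring nuclei, 27.3% to 56.3% for glutamatergic and GABAergic, 29.4% to 58.5% for astrocyte, 41.7% to 57.9% for oligodendrocyte, 0% to 42.9% for microglia and 12.2% to 20% for housekeeping genes. The shares of the matched sets moved as well. Without AAV-GFP replicate 2, PVH transcription factors had 68.2% against 64.7% in matched sets and PVH neuropeptide genes 50% against 49.8%. Without AAV-Cre replicate 1 these were 31.2% against 43.5% and 36.8% against 40%. The motif test and its alternatives were not run, because no genome sequence was used here.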

Other observations

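Some regions open in all 4 libraries ranked far apart in the groups. These genes were chosen after their values were seen. The region in Lmx1b, a LIM homeodomain gene, stood at percentiles 95 and 82.7 in the controls and 10.7 and 10.4 after AAV-Cre, and that in P2rx7, an ATP-gated channel gene, at 84.1 and 96.9 against 14.3 and 13.2. In the other direction, the region in Fam210b went from 11.1 and 36.6 to 93.5 and 85.9, and that in Rpsa, a ribosomal protein gene, from 31.1 and 31.4 to 91.2 and 96.3. A region 27817 bp from Gad2, which encodes a GABA-synthesising enzyme, stood at 30 and 42.1 in the controls and 97.9 and 98.9 after AAV-Cre. In 5771 of 14634 shared regions (39.4%) the ranks of the groups did not overlap, where chance gives 33.3% and the other splits gave 29.5% and 30.9%.

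All tests in the next paragraphs were chosen after the result was seen. Control-specific regions outnumbered Cre-specific regions 9.71 to 1. Fewer called peaks in the AAV-Cre libraries may account for much of this, since 0.223% of regions in the strongest 10% of both control lists were absent after AAV-Cre and 65.4% of the weakest. A genuine drop in accessibility in a minority of cells would also remove weak peaks first, and neither the depth nor whether it was made equal is known here, which would help to part them. Loss concentrated at PVH and melanocortin genes was tested by pooling 3 lists, where 24.7% of 89 regions were absent against 27.5% in matched sets (19.1 to 36, permutation p = 0.6). That range leaves a modest excess or deficit at these genes open, and loss of Otp itself remains an untested explanation of the whole.

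Strong control-specific regions clustered at the ends of X and Y, from Mid1 on X and past 90 Mb on Y, sequence that the sex chromosomes partly share. Regions on X and on Y may therefore hold reads of the same sequence, so their counts and tests are not independent of each other. As deposited, 59.5% of control-shared regions at the ends were absent after AAV-Cre against 27% elsewhere, and 4 of 14 against 3 of 3121 in the strongest 10% of both control lists. Whether weak peaks missed in shorter lists were the whole cause cannot be decided by a test on these ends. The ends were picked because strong control-specific regions of these same lists lay there, so a raised share and a small p follow in part from the choice. Equal length lowered absence elsewhere to 12.1%. At the ends 6 of 12 regions on X (Fisher's exact p = 0.0015) and 10 of 19 on Y (Fisher's exact p = 2.2e-05) were still absent. Regions are also not replicates, and the strongest 10% then held 1 of 10 against 1 of 1712. AAV-Cre libraries without a Y chromosome are excluded. At least 7 of 9 regions on Y below 1 Mb had a peak in each AAV-Cre library. These regions ranked stronger after AAV-Cre, at median within-list percentiles of 3.88 and 2.95 against 18 and 17.6 in the controls. The greater length of the control lists does not give this, since the same rank has a lower percentile in a longer list. A different mix of sexes, which the labels do not give, stays open, although less Y in the AAV-Cre mice would weaken these regions. Fewer copies of the ends in the AAV-Cre mice could lower these peaks and stay open along with loss of Otp, since no genomic input was used here. Of 13 regions kept in all 4 libraries, 8 ranked weaker in both AAV-Cre libraries and 3 ranked stronger. Those on X at 170758181 and 170880928 stood among the strongest ranks in every library. They shifted by -0.0308 and -0.349 percentile points, so neither showed the fall that fewer copies of the whole ends predicts. Regions on X at 169997416 and 170009755 had like ranks in the controls, at 0.239 and 0.226 and at 0.178 and 0.123. After AAV-Cre these stood at 17.6 and 25.8 and at 11.4 and 15.7. Rank does not measure signal, so a fall in signal at 170758181 and 170880928 cannot be excluded. The region on Y at 90793243 shifted by -40.7 points, which fewer copies of the whole ends would not give.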
